A study of Mus musculus with 2 samples.

How the data were processed

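Single-cell RNA sequencing was done on knee joints of mouse pups at postnatal day 7, from wild-type mice and mice lacking Col12a1, the gene of the fibril-associated collagen XII. Per the labels' protocols, joints of both sexes were digested for 6 h in collagenase II at 4 mg/mL, cells were strained, and 3' libraries were made with the 10x Genomics v3 chemistry. The labels describe 2 experiments, with 1 library per genotype in the first and 2 per genotype in the second, merged with Cell Ranger 7.0.0. The build was mm10, per the submitters' processing notes. Whether intronic reads were counted is not given in the sources used here.

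The deposited matrix holds whole-number UMI counts, not normalised, for 32285 genes in 24203 barcodes. Of its gene IDs, 32158 were found in the GENCODE M21 annotation of the same build, which gave the coordinates. Each barcode ends in 1 or 2, which parts the cells into barcode sets 1 and 2. The labels describe 3 libraries per genotype, more than these barcode endings tell apart. Whether a set pools several libraries, or some are absent from the matrix, is not given in the sources used here. No label used here ties a set to a genotype or an experiment. The matrix was therefore treated as 1 sample holding cells of both genotypes, the planned comparison of wild type with knockout was not run. Set values are given beside some of the joint values, chiefly those that leaving out a set moved by over 1.5 times. Neither Col12a1 counts nor barcode order was used to assign a genotype.

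Cells with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs were kept. Scrublet, run in scanpy 1.11.5 on each set, called 72 of 7160 cells (1.01%) in set 1 and 6 of 8014 (0.0749%) in set 2. Its automatic score thresholds were 0.264 in set 1 and 0.512 in set 2. Rates this low make it likely that doublets remain in both sets, above all in set 2. Why the rates were low was not tested. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2, seed 1) gave 30 clusters. The 12 fixed gene lists, all collagens, mitochondrial and ribosomal protein genes, Xist and Y-linked genes, 327 genes in all, were left out of clustering, so that the genes compared did not define the classes. Components were rounded to 4 decimals to make reruns identical, a step added after the first clustering had been seen and which moved cells between clusters.

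Cell type markers, gene lists, the rule of size and the rule for named genes were fixed before the data were examined, but the rule that turns markers into a name was not. The first rule asked for a mean marker log2 fold of at least 1 over all other cells and 3 detected markers above 0. It was replaced after its clusters, and their Col12a1 levels in each barcode set, had been seen, because it left the cluster led by Sfrp4 unnamed and named the cluster led by S100a4 after the rounding but not before. The rule that replaced it did not remove this dependence: with unrounded components the tenocyte-like or ligament-like class was 3.29% of cells under either rule, against 7.88% with rounding. Cut-offs on a count of markers, on a share of markers and on a mean of 1.5 were also looked at. The rule used here names a cluster for the class with the highest mean if the median marker log2 fold is at least 1 and 3 markers, each in at least 10% of cells, have a log2 fold of at least 1, with 10 CPM added to both sides. It puts cluster 5 (led by Sfrp4, 4.35% of set 1 and 6.68% of set 2) in the fibroblast-like class and cluster 9 (led by S100a4, 5.78% and 4.05%) in the tenocyte-like or ligament-like class. The first rule, the mean of 1.5, unrounded components and other seeds were run as alternatives chosen after seeing the data.

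Levels are UMIs summed over a class per 1000000 UMIs of that class (CPM), computed from the deposited counts, with exact Poisson intervals. Shares have exact Clopper-Pearson intervals. For each connective tissue class the CPM was divided by that of the other connective tissue classes pooled, with the exact conditional binomial interval. A gene was called higher or lower with 100 or more UMIs on both sides together, a ratio of at least 2 or at most 0.5, an interval without 1, and the same direction in both sets. All intervals are at the 95% level and cover counting error only. Cells are not replicates, so no p-value is given. For each list the median log2 ratio was ranked among 10000 random lists matched on expression. A class at 0 UMIs was set to 3 counts for bounds. To compare shares of cells with a UMI, cells were thinned to 2000 UMIs. Named genes are Col12a1, the fibril-associated collagens, the 5 highest and 3 lowest list genes of each class, the 2 most abundant genes of each list and the 5 leading genes of each unnamed cluster. Fos, Fosb, Ier3, Ctsk, Acp5, Il6, C1qa, the sex-linked genes and the genes leading named clusters fall outside that rule and were chosen after their values were seen.

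The ratio, its interval and the rule of size were tested on simulated sums with 200 changed genes per class. The sums were Poisson draws, with no spread between cells and the same rates in both sets. The interval assumes this model, so its coverage and the few false calls were largely set in advance. They do not show how the rule behaves where cells or sets vary more. For osteoblast-like cells, over 14409 genes, all simulated 4-fold changes were called, 2% of the 1.5-fold ones and 0.232% of unchanged genes, and 95.6% of the intervals held the true ratio. For the smallest connective tissue class, synovial lining fibroblast-like cells, over 14413 genes, 98.0% of 4-fold rises, 88% of 4-fold falls and 0.746% of unchanged genes were called. Alternatives covered the cell filters, doublets, resolution, components, the genes used for clustering, centring per set, leaving out each set, the mean over cells, thinning and the rule of size. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, igraph 0.11.9 and scikit-learn 1.9.0 were used.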

Results

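The data are 257619292 UMIs from 24203 barcodes of knee joint cells of wild-type and Col12a1 knockout mice at postnatal day 7, in 1 merged matrix. Barcode set 1 holds 11906 cells with a median of 7369 UMIs, and set 2 holds 12297 with a median of 7212. After filtering, 15096 cells remained, 7088 in set 1 (median 10895 UMIs) and 8008 in set 2 (median 9620.5 UMIs). The genotype of a set is not given in the sources used here, so levels below describe a mixture of both genotypes, without replicates. The knocked-out gene's counts could not check the genotype labels for the same reason.

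The first question was which cells the digested joints held. Fibroblast-like cells were the largest class, at 22.5% of cells (95% interval 21.8 to 23.2), followed by neutrophil-like (13.5%), erythroid-like (11.7%), chondrocyte-like (8.89%) and muscle progenitor-like cells (8.59%). Tenocyte-like or ligament fibroblast-like cells made up 7.88%, osteoblast-like cells 3.22% and synovial lining fibroblast-like cells 1.04%. B cell-like cells were 6.91% (4.51% of set 1 and 9.03% of set 2) and macrophage-like cells 4.87%. The fibroblast-like share was 13.8% with at least 1000 genes and 2000 UMIs, 14.5% at a resolution of 2 and 9.20% with a stricter naming rule, under which neutrophil-like cells were the largest class. The osteoblast-like share was 1.98% with at least 200 genes and 500 UMIs, 1.96% at up to 5% mitochondrial UMIs and 2.08% with components centred per set. The connective tissue classes together were 43.5% of cells, 42.6% of set 1 and 44.3% of set 2.

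Smaller classes were skeletal myofibre-like (1.70%), endothelial-like (1.60%), monocyte-like or dendritic-like (1.35%), mast cell-like (0.821%), pericyte-like or smooth muscle-like (0.755%), Schwann-like (0.662%) and T-like or NK cell-like cells (0.457%). Erythroid-like cells were 15.6% of set 1 and 8.33% of set 2, and muscle progenitor-like cells 5.63% and 11.2%. Fibroblast-like cluster 3 was led by the cytokine and acute phase genes Cxcl5, Csf2, Ptx3, Saa3 and Ccl2, and macrophage-like cells by Ccl4 and the interferon gene Ifnb1. Cluster 19 stayed unnamed and was led by Ppbp, Car1, Pf4, Ctla2a and Ism2. The other unnamed cluster, 24, was led by Dnah12, Wdr95, 6030407O03Rik, Kcnu1 and Cx3cr1. No cluster was named hypertrophic chondrocyte or osteoclast. The connective share depended on the naming rule, which was set after the data were examined: it was 37.9% under the rule used first and 25.4% when a mean marker log2 fold of 1.5 was also required.

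The second question was which joint cells held Col12a1 transcripts. Col12a1 (ENSMUSG00000032332) lies on the minus strand of chromosome 9, 79598991 to 79718831 in mm10, and the antisense gene 4930562D21Rik lies within it. Its level was highest in osteoblast-like cells, at 936 CPM (918 to 955), then 418 CPM (409 to 427) in tenocyte-like or ligament-like cells, 208 CPM in chondrocyte-like cells and 93.3 CPM in fibroblast-like cells. Pericyte-like or smooth muscle-like cells had 116 CPM (59.3 in set 1 and 178 in set 2) and Schwann-like cells 74.3 CPM (28.5 and 105). Synovial lining fibroblast-like cells, which make the joint lubricant Prg4, had 23.6 CPM (18.7 to 29.4), at 15.4 CPM in set 1 and 27.6 CPM in set 2. Neutrophil-like, erythroid-like and B cell-like cells, which should lack the gene, together had 13.8 CPM (12.62 to 14.95). The synovial level was above theirs over both sets, at a ratio of 1.72 (1.34 to 2.18), and in set 2, at 1.96 (1.46 to 2.59). In set 1 it was not above theirs, at a ratio of 1.14 (0.657 to 1.86). B cell-like cells, the highest of these blood classes, alone had 20.4 CPM (17.2 to 24.1), which overlaps the synovial interval over both sets. In set 2 the intervals also overlapped, at 16.5 to 25.3 in B cell-like and 21.2 to 35.4 in synovial lining fibroblast-like cells.

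Within the tenocyte-like or ligament-like class, Col12a1 was at 901 CPM in cluster 14, led by the tendon genes Tnmd, Kera and Scx, and at 155 CPM in cluster 9, led by S100a4. Unnamed cluster 24 had 312 CPM. Osteoblast-like cells held 30.4% of all Col12a1 UMIs in kept cells, tenocyte-like or ligament-like cells 26.2% (17.4% in set 1), fibroblast-like cells 17.3% (22.2% in set 1, above the tenocyte-like or ligament-like class there) and chondrocyte-like cells 16.3% (10.7% in set 1). After thinning to 2000 UMIs, 55.5% of osteoblast-like cells (50.9 to 60.0) had a Col12a1 UMI, 33.3% in set 1 and 84.1% in set 2. In cluster 14 this share was 69.9% (65.5 to 74.1), 27.7% in set 1 and 85.9% in set 2. Over both sets together it was thus higher in cluster 14 than in osteoblast-like cells, but in neither set alone. In set 1 the intervals were 20.2 to 36.2 in cluster 14 and 27.8 to 39.3 in osteoblast-like cells, and in set 2 they were 81.6 to 89.5 and 78.4 to 88.8. Set 2, where the shares were higher, held 323 of 455 cells of cluster 14 and 212 of 486 osteoblast-like cells. The thinned share was 39.7% of tenocyte-like or ligament-like cells (13.8% and 60.5%), 30.2% of chondrocyte-like cells (8.01% and 50.4%) and 15.6% of fibroblast-like cells (8.87% and 21.2%). It was 1.98% in the blood classes (2.62% and 1.04%), where 461 cells were too shallow, against 5 osteoblast-like cells. At 1000 UMIs it was 18.5% of chondrocyte-like cells (3.69% and 33.1%) and 9.16% of fibroblast-like cells (5.69% and 11.9%). Unthinned, the shares were 86.0% of osteoblast-like cells at a median of 16594 UMIs and 5.65% of blood cells (7.81% in set 1 and 3.23% in set 2) at a median of 5382.5 UMIs.

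Both barcode sets had the highest Col12a1 level in osteoblast-like cells, at 294 CPM in set 1 and 1884 CPM in set 2. The tenocyte-like or ligament-like class had 91.9 and 753 CPM, its cluster 14 had 207 and 1276 CPM and its cluster 9 had 54.8 and 299.98 CPM. The class differed in make-up, with 132 cells of cluster 14 and 410 of cluster 9 in set 1 and 323 and 324 in set 2. Unnamed cluster 24 had 116 and 527 CPM, chondrocyte-like cells 41.9 and 412 CPM, fibroblast-like cells 42.3 and 139.7 CPM, and the blood classes 13.4 and 14.1 CPM. At a resolution of 0.5 and with 15 components no cluster was named osteoblast-like, and the tenocyte-like or ligament-like class was then highest. The 418 CPM of the tenocyte-like or ligament-like class rests on which cells joined it: the class was 7.88% of cells here, but 3.30% at 829 CPM with clustering seed 5 and 3.29% at 819 CPM with unrounded components.

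**Figure D1:**
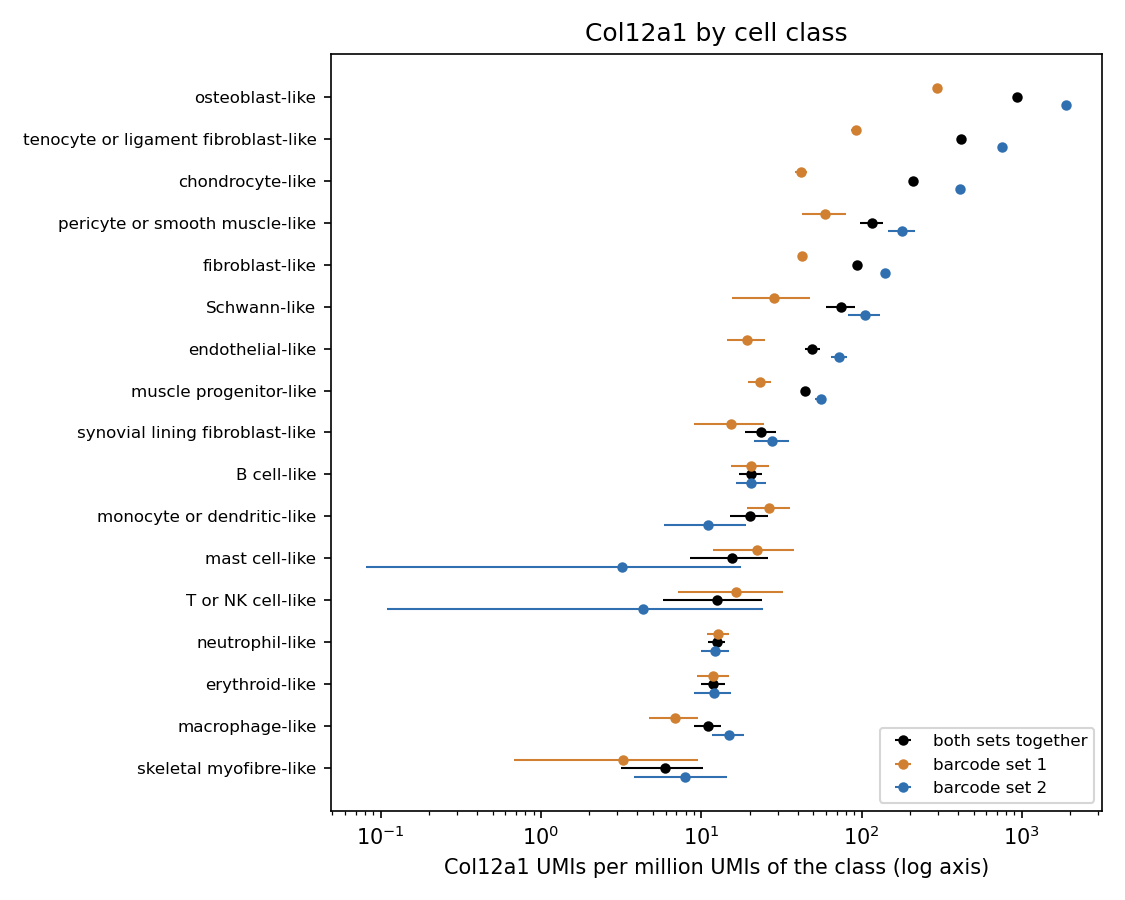
Col12a1 UMIs per 1000000 UMIs of each cell class, on a log axis, with exact 95% Poisson intervals that cover counting error only; black points are both barcode sets together, orange points set 1 and blue points set 2. Osteoblast-like cells are highest at 936 CPM. Over both sets together, neutrophil-like cells lie at 12.5 CPM, erythroid-like cells at 11.9 CPM and B cell-like cells at 20.4 CPM.

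The third question was how collagens and other matrix genes were shared among the connective tissue classes. Of 190 list genes with enough UMIs, 35 were higher and 70 lower in chondrocyte-like cells than in the other connective tissue classes, 32 and 59 in fibroblast-like cells, 29 and 39 in osteoblast-like cells, 13 and 29 in tenocyte-like or ligament-like cells, and 9 and 91 in synovial lining fibroblast-like cells. Of all 14402 genes with enough UMIs, calls in the same order were 1381 and 2890, 1264 and 1738, 1074 and 1412, 400 and 1389, and 1498 and 2338. The classes thus differed in many other genes too. In synovial lining fibroblast-like cells the share called higher was smaller among list genes than among all genes. The 13 higher calls in tenocyte-like or ligament-like cells were 22 without set 1, and 22 to 37 in 14 alternatives. The 9 in synovial lining fibroblast-like cells were 14 with 15 components and 15 when clustering used the list genes. Over all classes, 194 list genes had enough UMIs, 110 of them peaked in a connective tissue class, and 151 peaked in the same class in both sets. Of 60 pairs of a list and a class, 41 lay outside the central 95% of random lists, 12 above and 29 below. Lists of independently drawn genes would give 3. Genes of a list can vary together, and each class is also in the pool that the others were compared with. The count of 41 is therefore a description and not a test.

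Chondrocyte-like cells had the collagens of cartilage fibrils. Col9a3 was 504-fold higher (469 to 543), Col9a1 414-fold, Col2a1 403-fold at 42326 CPM (655-fold in set 1 and 307-fold in set 2), and Col9a2 263-fold. Chondrocyte-like cells held 1095907 of 1130037 Col2a1 UMIs in kept cells and were in the pool for every other class. The falls of Col2a1, Col9a1, Col9a2 and Col9a3 in other classes, given below, therefore mostly reflect the chondrocyte-like cells in that pool. Epyc, a small leucine-rich proteoglycan, was 53.1-fold higher, Comp 14.9-fold and Timp1, a protease inhibitor, 6.72-fold. Aspn was 40.6-fold lower, Col22a1 38.8-fold (20.6-fold in set 1 and 74.5-fold in set 2) and Col6a6 31.1-fold. Of the 17 elastic fibre and microfibril genes none was higher and 14 were lower, with Mfap5 30.6-fold and Fbn1 15.3-fold lower. Of 28 cell cycle genes 7 were higher, among them Top2a at 2.33-fold (1.99-fold in set 1, under the ratio of 2), and none was lower, although 2 were lower in set 1 alone. Col2a1 was also at 3145 CPM in mast cell-like cells, a class that should lack it, with 4807 CPM in set 1 and 35.2 CPM in set 2.

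Fibroblast-like cells stood out by elastic fibre genes, of which 10 of 17 were higher and 2 lower, above all 10000 random lists. Mfap5 and Fbn1, parts of the microfibril, were 12.1-fold (11.9 to 12.3) and 7.79-fold higher, and Efemp1 was 13.4-fold higher. Col6a5 and Col6a6, chains of collagen VI, were 14.2-fold and 9.92-fold higher. Col6a5 was at 8.16 CPM, with 11.2 CPM and 22.6-fold in set 1 and 5.40 CPM and 8.10-fold in set 2. Tnxb, a tenascin, was 5.89-fold higher. Col2a1, Col9a1 and Col9a3 were 608-fold, 419-fold and 415-fold lower, and Col12a1 was 4.28-fold lower (2.54-fold in set 1 and 5.22-fold in set 2). Of 28 cell cycle genes 15 were lower and none higher.

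Osteoblast-like cells had the collagenase Mmp13 52.0-fold above the other connective tissue classes (49.2 to 54.9), at 23.9-fold and 482 CPM in set 1 and 144-fold and 1049 CPM in set 2. The tenascin Tnn was 35.9-fold higher, 24.5-fold in set 1 and 77.0-fold in set 2. Col8a1 was 9.25-fold higher, the fibrillar collagen Col24a1 8.29-fold, Col12a1 5.25-fold (5.12 to 5.37), at 5.76-fold in set 1 and 6.21-fold in set 2, and Col16a1 2.96-fold. The Col12a1 ratio over both sets was thus below that of either set, and its counting interval held neither. The sets were unequally represented: osteoblast-like cells were 274 in set 1 and 212 in set 2, and the connective tissue classes together 3022 and 3547. Col1a1 and Col1a2, the chains of bone collagen I, were 2.33-fold and 2.03-fold higher. Serpinh1, a collagen chaperone, peaked here at 1584 CPM. Mmp9 was 32.7-fold higher at 156 CPM, while neutrophil-like cells had 445 CPM. The osteoclast markers Ctsk and Acp5 were at 337 and 26.4 CPM in osteoblast-like cells (Acp5 at 36.1 in set 1 and 12.2 in set 2), at 181 and 11.7 CPM in fibroblast-like cells and at 42.8 and 257 CPM in macrophage-like cells. Of 16 dissociation and immediate early genes 4 were higher (Fos, Fosb, Hspa1a, Hspa1b) and Ier3 was lower, but without set 1 none of these calls held, with Fos at 1.31-fold, while 9 were higher without set 2. Col2a1 was 53.7-fold lower (99.1-fold in set 1 and 31.3-fold in set 2) and Col9a3 41.7-fold lower (70.7-fold and 24.6-fold). Col19a1, with no UMI, was at least 3.61-fold lower, at least 1.63-fold in set 1 and at least 1.80-fold in set 2, a call that neither set gave alone.

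Tenocyte-like or ligament-like cells had Thbs4, a thrombospondin of tendon, 12.9-fold higher (12.6 to 13.2). Bmpr1b was 3.66-fold higher, Fmod, which binds collagen fibrils, 3.52-fold, Tgfbi 2.72-fold and Adamts3, a procollagen protease, 2.61-fold, but 1.27-fold in set 1 and 4.39-fold in set 2. Col1a1, Bgn and Col1a2 were 2.35-fold, 2.21-fold and 2.09-fold higher. Col12a1 was at 1.99-fold, under the ratio of 2 that a call needs (1.25-fold in set 1 and 2.16-fold in set 2), but 17 of 24 alternatives called it higher, at 3.93-fold with clustering seed 5. Col9a3 was 133-fold lower, Col9a1 91.5-fold (153-fold in set 2) and Col9a2 71.6-fold. The proteoglycan list had 2 higher (4 in set 2) and 2 lower of 11 genes, with a median log2 ratio of 0.36. Of 19 matrix proteases and inhibitors none was higher and 7 were lower (median log2 ratio -0.56), and of 17 elastic fibre genes none was higher, although 1 was in each set alone, and 4 were lower (median -0.42). Of 28 cell cycle genes 2 were higher (5 in set 2) and none lower, with a median of 0.46.

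Synovial lining fibroblast-like cells had Col22a1, a fibril-associated collagen of tissue junctions, at 1340 CPM, 97.7-fold above the other connective tissue classes (92.3 to 103). Colgalt2 was 9.39-fold higher (14.8-fold in set 1 and 6.81-fold in set 2), Tgfbr1 3.94-fold, Ccnb2 3.06-fold and Bmp4 2.90-fold, but Bmp4 was at 1.80-fold in set 1. All other fibril-associated collagens that were called were lower here, among them Col14a1 17.4-fold (88.8-fold in set 1 and 14.1-fold in set 2) and Col16a1 10.2-fold (18.4-fold and 8.55-fold). Col12a1 was also lower, at 23.6 against 251 CPM in the other connective tissue classes (77.6 in set 1 and 431 in set 2), but its level in set 1 was not above that of the blood classes, so no fold is given. Tnn was at 2 UMIs, both in set 2, a ratio of 0.00972 (0.00118 to 0.0351) over both sets and 0.0233 in set 2. Col6a5, with no UMI, was at least 5.04-fold lower, at least 2.09-fold in set 1 and at least 2.47-fold in set 2. Col4a6 also had no UMI and was at least 1.93-fold lower, a call that neither set gave alone. Col1a1 was 9.35-fold and Dcn 8.38-fold lower. This class had 157 cells.

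The fibril-associated collagens differed in where they peaked. Col9a1, Col9a2 and Col9a3 peaked in chondrocyte-like cells at 2656, 2080 and 3850 CPM, Col14a1 in tenocyte-like or ligament-like cells at 823 CPM, Col16a1 in osteoblast-like cells at 625 CPM and Col22a1 in synovial lining fibroblast-like cells. Col19a1 peaked in muscle progenitor-like cells at 102 CPM (97.47 to 106.8) and Col20a1 in Schwann-like cells at 206 CPM (182 to 234), against 7.54 CPM in the next class.

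The other lists split between classes. Of 19 matrix proteases and inhibitors, 6 were higher and 5 lower in fibroblast-like cells, and 3 were higher and 13 lower in chondrocyte-like cells, while Timp2 was at 1073 CPM in osteoblast-like and 1072 CPM in tenocyte-like or ligament-like cells. Of 16 collagen VI and basement membrane collagens, 6 were higher and 3 lower in fibroblast-like cells and 2 higher and 8 lower in osteoblast-like cells. Col6a1 and Col6a2 peaked in tenocyte-like or ligament-like cells at 1192 and 1030 CPM. Of 26 genes of collagen biosynthesis and crosslinking, 2 were higher (1 in set 1) and 13 lower in synovial lining fibroblast-like cells, and Pcolce peaked in fibroblast-like cells at 888 CPM. Of 21 TGF-beta and BMP family genes, 6 were higher and 5 lower in chondrocyte-like cells, where Tgfb2 peaked at 567 CPM. Of 8 collagen receptors, 1 was lower and none higher in fibroblast-like cells. Ddr2, a receptor for fibrillar collagen, peaked in synovial lining fibroblast-like cells at 626 CPM, and Itgb1 in pericyte-like or smooth muscle-like cells at 1048 CPM. Dcn peaked in fibroblast-like cells at 4833 CPM, Pcna in B cell-like cells at 193.6 CPM and Hspa1b in endothelial-like cells at 3201 CPM, although in set 1 Hspa1b was higher in osteoblast-like cells, at 2746 against 2591 CPM.

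**Figure D2:**
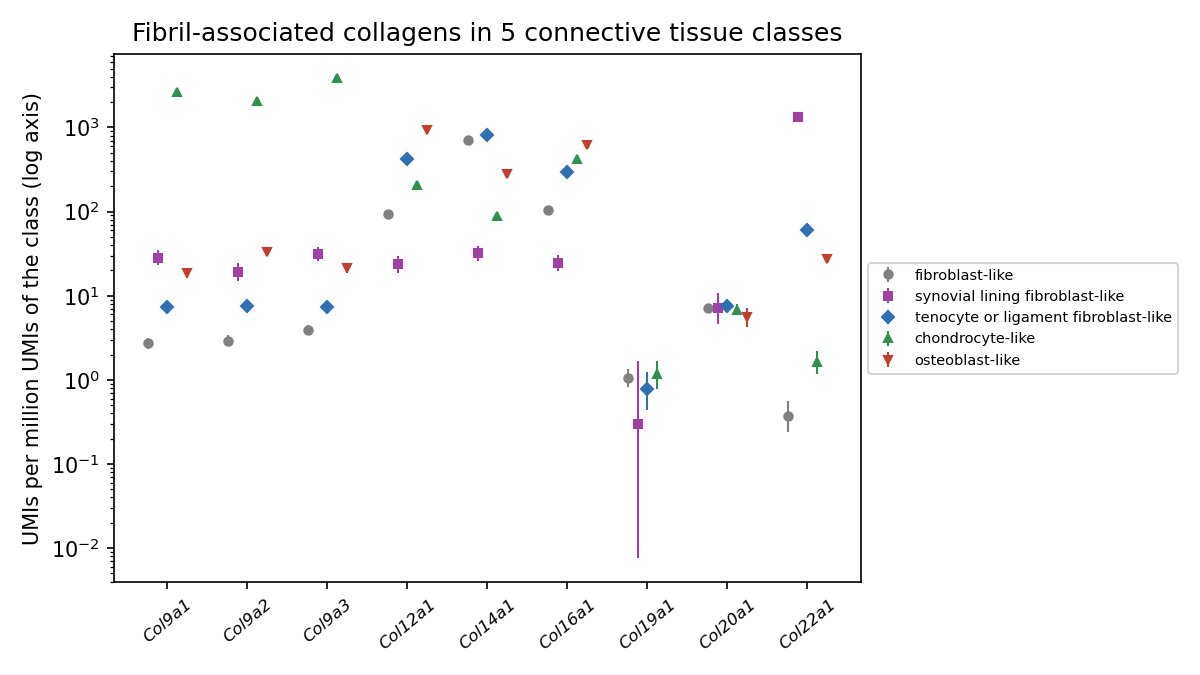
UMIs per 1000000 UMIs of 9 fibril-associated collagen genes in the 5 connective tissue classes, on a log axis, with exact 95% Poisson intervals that cover counting error only; genes at 0 UMIs in a class have no point. Col22a1 is at 1340 CPM in synovial lining fibroblast-like cells and Col9a3 at 3850 CPM in chondrocyte-like cells.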

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

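All tests in this part were chosen after the result was seen. Xist, the RNA of the inactive X chromosome, had 221 CPM over the deposited cells of barcode set 1 and 0.307 CPM over those of set 2, a signal outside the comparisons above. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y together had 98.6 CPM in set 1 and 166.5 CPM in set 2. A lower depth of set 2 is argued against: after thinning to 2000 UMIs, 17.0% of set 1 cells and 0.0263% of set 2 cells had an Xist UMI, a ratio of 646. Cells of male animals in set 2 are a candidate explanation, since 95.2% (94.0 to 96.2) of its cells with 20000 or more UMIs had a Y-linked UMI, although the interval reaches below the 95% that was asked. Among such deep cells without Xist the share was 95.2% in set 1 and 95.3% in set 2.

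Of the cells that failed the filters, 4273 had over 50% of their UMIs from the haemoglobin genes, a signal in cells that no comparison used. They were 47.3% of the 9029 failing cells, 51.4% in set 1 and 42.8% in set 2. No explanation was tested.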

How the results depend on the processing

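Alternatives with other naming rules, unrounded components, other clustering seeds, the highest doublet scores removed or cluster 9 left out were chosen after seeing the data, as were all alternatives for the ranks of list medians among random lists. Osteoblast-like cells had the highest Col12a1 level under 20 of the 22 alternatives that recomputed levels. At a resolution of 0.5 and with 15 components no osteoblast-like class was found, which left no value for it. The cause was not tested for any of the values that follow.

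The connective share of 43.5% became 39.7% with at least 200 genes and 500 UMIs, 36.7% with at least 1000 genes and 2000 UMIs, 37.2% at up to 5% mitochondrial UMIs, 31.8% at a resolution of 2, 39.9% with 15 components and 34.2% when clustering used the list genes. It was 42.6% without set 2 and 44.3% without set 1. It was 25.4% with a mean marker log2 fold of 1.5, 37.9% with the naming rule used first, 39.3% with unrounded components, 33.7% with both of these, 39.8% with seed 5, 33.2% without the 6% highest doublet scores and 40.6% without cluster 9.

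Col12a1 in osteoblast-like cells, 936 CPM, was 1025 CPM with at least 200 genes and 500 UMIs, 877 CPM with at least 1000 genes and 2000 UMIs, 1038 CPM at up to 5% mitochondrial UMIs, 915 CPM with doublets kept, 911 CPM at a resolution of 2, 887 CPM when clustering used the list genes, 1033 CPM with centred components and 1088 CPM as a mean over cells. It was 294 CPM without set 2 and 1884 CPM without set 1, so each set decides it. It was 905 CPM with unrounded components under either naming rule, 895 CPM with seed 2 and 891 CPM with seed 5. In the tenocyte-like or ligament-like class, 418 CPM became over 700 CPM in 12 of 22 alternatives. Its Col12a1 ratio of 1.99 ranged from 1.25 without set 2 to 6.86 at a resolution of 0.5, and 17 of 24 alternatives called it higher. With 15 components synovial lining fibroblast-like cells had 71.9 CPM in place of 23.6 CPM.

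The total of 406 calls of list genes became 209 at a ratio of 4 and 300 UMIs. It stayed within 1.5 times in all other alternatives, among them a ratio of 1.5 and 30 UMIs, which gave 591. The 13 higher calls in tenocyte-like or ligament-like cells became 22 to 37 in 14 alternatives and the 29 lower ones 46 with 15 components, the 9 higher calls in synovial lining fibroblast-like cells 14 and 15 in 2, and the 32 in fibroblast-like cells 49 with a mean marker log2 fold of 1.5. At a ratio of 4, higher and lower calls were 1 and 12 in tenocyte-like or ligament-like, 2 and 59 in synovial lining fibroblast-like, 15 and 28 in fibroblast-like, 16 and 43 in chondrocyte-like and 10 and 23 in osteoblast-like cells. At a ratio of 1.5, higher calls were 45, 24, 46, 54 and 60 in the same order, and 46 were lower in the first class. The pairs of list and class outside the central 95% stayed within 1.5 times of 41. Of the single values, 165 moved and 310 did not. A count moved if it changed by over 1.5 times. A share, a Col12a1 level or the Col12a1 ratio moved if it left the 95% counting interval of its main value, which small changes can do. The comparison of genotypes with its alternatives was not run. No paired analysis was possible because no cell could be tied to a genotype. The synovial lining fibroblast-like class rests on 157 cells, where 88% of 4-fold falls were called in a simulation without spread between cells.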

Other observations

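The test of macrophage RNA in this part was written before its result was seen, the other tests after. In fibroblast-like cluster 3, Csf2 was at 853 CPM, 41.4-fold above fibroblast-like clusters 1 and 5 (38.4 to 44.7), Csf3 36.0-fold (23.9-fold in set 2), Cxcl5 30.1-fold, Ptgs2 13.0-fold, Saa3 11.4-fold, Ccl2 6.58-fold at 19729 CPM, Ptx3 6.45-fold and Il6 4.09-fold. Cluster 3 was 9.38% of set 1 and 6.22% of set 2, so both sets held it. Some of these genes lead the cluster and helped to define it, so their folds describe it. An immediate early or heat shock response to tissue digestion is argued against, since that list had a median log2 ratio of -1.73 in cluster 3, at percentile 0 of matched random lists, with Fos at 33.1 against 538 CPM and Hspa1a at 101 against 3051 CPM, although Ier3 was 4.13-fold higher. This explanation was narrowed to early genes after the result was seen, and a later response to the 6 h digestion was not tested and stays open. RNA from macrophages, or doublets with them, is argued against by macrophage markers at a median ratio of 0.571, with C1qa at 0.216 CPM (0.0623 in set 1 and 0.426 in set 2) against 1137 CPM in macrophage-like cells. No biological explanation was tested.

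Col12a1 differed between the unmapped barcode sets in connective tissue clusters. In osteoblast-like cluster 13 it was at 294 CPM in set 1 and 1884 CPM in set 2, in cluster 14 at 207 and 1276 CPM, in chondrocyte-like cluster 2 at 41.9 and 412 CPM, and in synovial lining fibroblast-like cluster 26 at 15.4 and 27.6 CPM, and the interval of the ratio lay above 1 in all 8 connective tissue clusters. By the ratio of set 2 to set 1, Col12a1 ranked 4 of 10268 genes in chondrocyte-like cells, 12 of 8632 in osteoblast-like, 12 of 10075 in tenocyte-like or ligament-like and 44 of 12438 in fibroblast-like cells. The last 2 classes differ in make-up between the sets: cluster 14 had 132 of 542 and 323 of 647 tenocyte-like or ligament-like cells, and cluster 3 had 665 of 1476 and 498 of 1919 fibroblast-like cells. A difference in depth is argued against by thinned shares of osteoblast-like cells with a UMI, whose ratio was 2.52. More free RNA in set 2 is argued against by a ratio of 1.05 (0.884 to 1.25) in the blood classes. A different mix of sexes is argued against by a ratio of 6.79 (6.30 to 7.33) among osteoblast-like cells with a Y-linked UMI and no Xist. Genotype, which the design names, and the experiment or library stay open and untested, since no label ties a set to them, and a genotype is not assigned here. A different mix of cells within clusters was not tested and stays open.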
